A study of Brassica napus with 4 samples.

How the data were processed

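Small RNAs were profiled in siliques, the seed pods, of 2 oilseed rape (Brassica napus) cultivars grown in the field at 2 locations. Per the labels, XZ088 has a low and XZ366 a high seed oil content, and each was planted at Nanjing and at Lhasa. Each of the 4 combinations had 1 library, made from siliques of 3, 7, 14 and 21 days after flowering pooled together. RNA of 15 to 30 nt was cut from a 15% gel, ligated to adapters and sequenced on an Illumina Solexa instrument, per the labels' protocols.

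The deposited values are raw counts: per the file headers, each table lists a distinct sequence (here called a tag) and its number of reads, with no scaling to depth. The tags were 15 to 30 nt long. Adapter trimming, quality filtering, any mapping step and the genome build are not given in the sources used here. The tables held 6338565 reads for XZ088 at Nanjing, 6466930 for XZ366 at Nanjing, 2252748 for XZ088 at Lhasa and 3823610 for XZ366 at Lhasa. The Lhasa libraries were therefore the shallower pair, and 1 read weighed more there. A count of 0 allows up to 3 reads, which is 0.473, 0.464, 1.33 and 0.785 RPM in the same order, where RPM is the read count scaled to all reads of its library. Reads were amplified without molecular identifiers, so all intervals and floors cover counting error only.

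No genome was used, so tags were identified by sequence alone and no position is given. A list of 47 mature sequences from 39 families of miRNAs and a trans-acting siRNA was written from known plant sequences before the data were examined. A tag of 19 to 24 nt belonged to a family if its first 18 nt equalled those of a listed sequence, so that reads of near-identical family members were summed and cannot be divided between loci. Families with near-identical sequences, such as miR156 and miR157 or miR165 and miR166, were kept apart by those 18 nt. Lists of 20 passenger-strand sequences, 7 starts of transfer RNAs, the 5.8S ribosomal RNA and 7 animal or monocot miRNAs were fixed at the same time. Lists of families by function were also fixed: development, auxin, nutrient supply, silencing machinery, triggers of trans-acting siRNAs, resistance genes and young Brassicaceae families. The last list also held miR157, although its sequence is near-identical to that of miR156.

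Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation and the quasi-likelihood fit. Families entered beside all other tags, after filterByExpr with a minimum count of 10. The additive design held location and cultivar, so each level had 2 libraries and 1 residual degree of freedom, and the error term was the interaction of cultivar and location. Spread was shared across features, with a prior of 14.9 degrees of freedom and a common dispersion of 0.0956. Adjusted p-values follow Benjamini and Hochberg over all features, with a threshold of 0.05, and a second set was adjusted over the list alone. The standard error of a log2 fold change was taken as its size divided by the root of the F statistic. All tests were two-sided. Nothing in the labels says that libraries of 1 level are biological repeats of each other. The p-values set an effect against a spread drawn mostly from all features, by 14.9 prior against 1 residual degree of freedom. A small p therefore does not show that a feature's own effect was alike in the 2 pairs of libraries.

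Direct ratios of 2 libraries are ratios of RPM, with an exact conditional binomial 95% interval. They compare the libraries, not the conditions, and have no p-value. Shares have exact Clopper-Pearson intervals and sums of reads exact Poisson intervals. TMM gave factors of 1.18, 1.15, 0.853 and 0.866 in the order above. It raised every Lhasa over Nanjing log2 fold by about 0.43 against scaling by total reads, as the median over all features moved from -0.46 to -0.028. Fitted location folds are relative to that scale.

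Agreement of the 2 pairs was measured across families with a mean of at least 10 RPM, on log2 of RPM plus 1, as Pearson's r and Spearman's rho with 100000 permutations of families. Each list's median log2 fold was placed among 10000 random lists of tags of the same size and mean abundance. The test was tried on simulated counts with 200 changed features. For cultivar, among 53806 features, it recovered 2% of those changed 2-fold, 16% at 4-fold, 78% at 8-fold and 94% at 16-fold, with 3 false calls. For location, among 53794 features, these shares were 2%, 16%, 74% and 96%, with 2 false calls. Changes of up to 4-fold were thus mostly beyond its reach for single tags of typical depth. With only 200 changed features the adjusted threshold was stricter than in the real fits, which called more.

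Families were named by a rule fixed before the data were examined. It took every family with an adjusted p under 0.05. It also took the 12 highest and 12 lowest additive folds among families of at least 5 RPM with the same sign in both pairs. Last came the 5 most abundant families, and, outside the list, the 3 tags in each direction with the smallest p. For differences between pairs, the 5 families with the largest difference were named. Alternatives were DESeq2 1.42.0, its size factors within edgeR, total-read scaling, no count filter, no block, other family definitions, families alone and each library left out. Chosen after seeing the data were libraries thinned to equal depth, and a fit without adapter-like tags, tags shorter than 18 nt and tags 1 mismatch from a tag at least 20 times as abundant, first outside the families and then within them too. Other steps used Python 3.11.15 with scipy 1.17.1.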

Results

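The study compared small RNA profiles of a low-oil and a high-oil rapeseed cultivar at a lowland and a high-altitude field location, to find small RNAs whose levels go with seed oil content and silique development. The 4 libraries held 18881853 reads in total, from 2252748 for XZ088 at Lhasa to 6466930 for XZ366 at Nanjing, in 5611153 distinct tags. Of these tags, 82.5% occurred in 1 library only and 3.25% in all 4. Tags seen once made up 76.3% and 76.7% of the tags of XZ088 and XZ366 at Nanjing, and 83.0% and 80.8% at Lhasa. There was 1 library per combination, so no level below has a replicate error.

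In all 4 libraries 24-nt small RNAs, the length of siRNAs that direct DNA methylation, were the largest class, and 21-nt small RNAs, the length of most miRNAs, formed a second peak in all but the XZ366 Nanjing library. The 24-nt class held 52.9% of reads (95% interval 52.9 to 53.0) in XZ088 and 50.9% (50.8 to 50.9) in XZ366 at Nanjing. At Lhasa it held 42.7% (42.6 to 42.8) in XZ088 and 44.3% (44.2 to 44.3) in XZ366. The 21-nt class took 13.3% and 12.9% at Nanjing and 17.8% and 17.3% at Lhasa, in the same order of cultivars. The ratio of 24-nt to 21-nt reads was therefore 3.99 and 3.95 at Nanjing and 2.40 and 2.56 at Lhasa. Between locations the 24-nt share differed by -10.2 points in XZ088 and -6.60 points in XZ366. Between cultivars it differed by -2.04 points at Nanjing and 1.58 points at Lhasa, with opposite signs. Without tags seen once the Lhasa sign turned, at 47.5% in XZ088 and 47.0% in XZ366, so that both differences were negative. Adenine was the first base of 50.3% and 49.1% of 24-nt reads at Nanjing and of 53.6% and 53.3% at Lhasa. Thymine, which stands for uracil, began 39.3% to 45.9% of 21-nt reads.

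**Figure D1:**
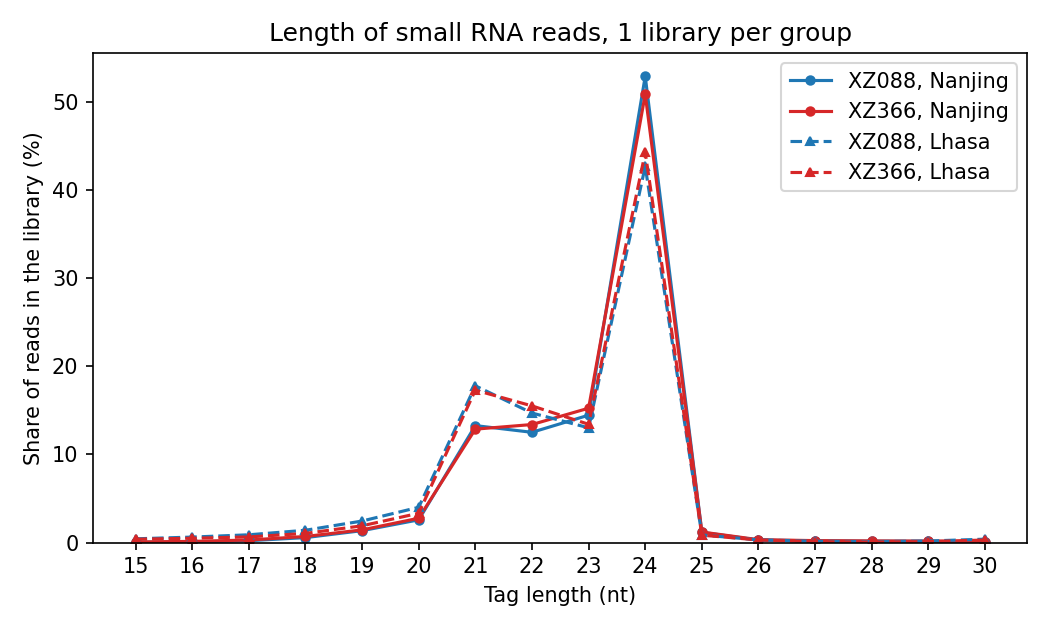
Share of reads (percent, y axis) by tag length (nt, x axis) in each of the 4 libraries, 1 line per library. The peak at 24 nt reaches 52.9% and 50.9% in the Nanjing libraries against 42.7% and 44.3% in the Lhasa libraries.

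Listed miRNA families made up a small part of the reads and a larger part at Lhasa. They summed to 15479 RPM (15382 to 15576) in XZ088 and 20428 (20318 to 20539) in XZ366 at Nanjing. At Lhasa the sums were 43431 (43160 to 43704) and 49187 (48965 to 49410). Most of the gap was miR167, a family that targets auxin response factor transcripts. It counted 6800 and 11155 RPM at Nanjing and 32192 and 38324 at Lhasa. Without miR167 the sums were 8679 and 9273 at Nanjing and 11239 and 10863 at Lhasa. The next most abundant families were miR168, which targets an ARGONAUTE transcript, at 5438 to 6828 RPM, and miR172 at 619 to 1850. miR170, miR173, miR398, miR472 and miR860 had 0 reads in all 4 libraries, which allows up to 1.33 RPM in the shallowest. Starts of transfer RNAs took 0.144% to 0.223% of reads and 5.8S ribosomal RNA 0.335% to 0.490%, with no common direction between locations in the 2 cultivars.

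Location was compared first, as Lhasa over Nanjing with cultivar as a block. Of 28 families tested, 14 rose at Lhasa, 1 fell and 13 did not pass the threshold over all 63623 features (edgeR, adjusted p under 0.05). Adjusted over the list alone, 15 rose and 2 fell. Fitted and scaled without the other tags, 7 families passed as higher and 4 as lower, and 7 of the 15 calls ended. miR827, a regulator of phosphate homeostasis, rose by 3.71 on the log2 scale (SE 0.44, adjusted p = 1.04e-04), and by 3.04 to 4.42 with each library left out. Here and below, a fold with a library left out is set by the pair of libraries that stays whole. Apart from scaling, such a range restates the ratios within the pairs and is no separate check. miR827 went from 6.78 to 105.6 RPM in XZ088 and from 14.5 to 90.2 in XZ366. miR2111, another phosphate-linked family, fell by 3.75 (SE 0.60, adjusted p = 8.65e-04). It counted 10.6 and 26.4 RPM at Nanjing against 0.444 and 1.57 at Lhasa, where it rested on 1 and 6 reads. Its Lhasa over Nanjing ratio was 0.0420 in XZ088 (counting interval 0.00105 to 0.242) and 0.0593 in XZ366 (0.0215 to 0.132).

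Among the 18 families of the development list, 14 were tested, 8 rose, none fell and 6 did not pass. Their median log2 fold of 1.56 was above all 10000 random lists of tags of like abundance, but so was the median of all 28 tested families, at 1.37, so the placement is not particular to this list. The 8 included miR167, at 2.45 (SE 0.40, adjusted p = 9.69e-04), and miR169, which targets subunits of a CCAAT-binding factor, at 2.48 (SE 0.37, adjusted p = 5.88e-04), although with 1 mismatch allowed its fold was 0.61 and not called. miR394, which targets an F-box transcript, rose by 2.98, miR171, directed at GRAS transcription factors, by 2.45 (1.54 to 3.37 with each library left out), and miR160, directed at auxin response factors, by 2.24. miR172, which targets APETALA2-like factors, rose by 1.67, miR164, directed at NAC factors, by 1.61, and miR824, directed at a MADS-box transcript, by 1.51. Adjusted p among these 6 ran from 9.86e-04 for miR394 to 0.00973 for miR824. miR166 and miR157 had log2 folds of -0.71 (adjusted p = 0.141) and -0.82 (adjusted p = 0.0949) in the same fit, and did not pass. miR165 had -0.19, miR396 1.24, miR159 0.56 and miR156 0.93, none past the threshold, and with each library left out miR396 ran from 0.47 to 1.88 and miR156 from 0.035 to 1.83. The miR165 fold changed sign without either XZ366 library, with 1 mismatch and at equal depth. That of miR159 did so without the count filter, with families alone and for exact sequences.

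Of 6 families in the auxin list, 4 rose and 2 did not pass: miR160, miR164, miR167 and miR393, which targets auxin receptor transcripts, at 1.95 (SE 0.57, adjusted p = 0.0250). The miR393 call ended with DESeq2, at 1.97, and at equal depth, at 1.73. miR390, which triggers trans-acting siRNAs, had -0.47 (adjusted p = 0.355), but -0.91 under total-read scaling and -1.35 with families fitted alone, where it was called, and the siRNA directed at auxin response factors had 0.067, which was -0.37 under total-read scaling. Of the silencing list, miR162, which targets DICER-LIKE, rose by 1.55, and miR403, which targets an ARGONAUTE transcript, by 1.80, while miR168 had 0.69 (adjusted p = 0.174). The miR168 fold turned negative without the count filter and with families fitted alone. Of 7 nutrient families 5 were tested. miR827 and miR399, which acts in phosphate supply, rose, the latter by 2.22 (SE 0.40, adjusted p = 0.00197), and miR2111 fell. The copper-linked miR397 and miR408 had 0.44 and 0.59 and did not pass. Of 5 families tested on the young Brassicaceae list, miR158 rose by 2.00 (1.52 to 2.48 with each library left out) and miR824 by 1.51, while miR157, miR391 at 0.15 and miR1885 at 0.24 did not pass. miR390 was the lone tested trigger and miR1885 the lone tested resistance family. The 15 called families moved the same way in both cultivars and kept their direction under total-read scaling, in which miR393 and miR824 no longer passed and miR157 and miR166 also passed as lower at Lhasa. Under that scaling the folds of miR391 and miR1885 were negative, at -0.29 and -0.20, as was the median of the young Brassicaceae list at -0.20, against 0.24 under TMM. Without the count filter 6 families passed, 5 higher and 1 lower at Lhasa. The calls of miR158, miR162, miR172, miR393, miR403 and miR824 ended both there and with families fitted alone, where their folds were 1.12, 0.67, 0.78, 1.08, 0.92 and 0.63. That of miR171 ended with families alone, at 1.57, and those of miR160, miR164 and miR167 without the filter, at 1.52, 0.89 and 1.73.

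**Figure D2:**
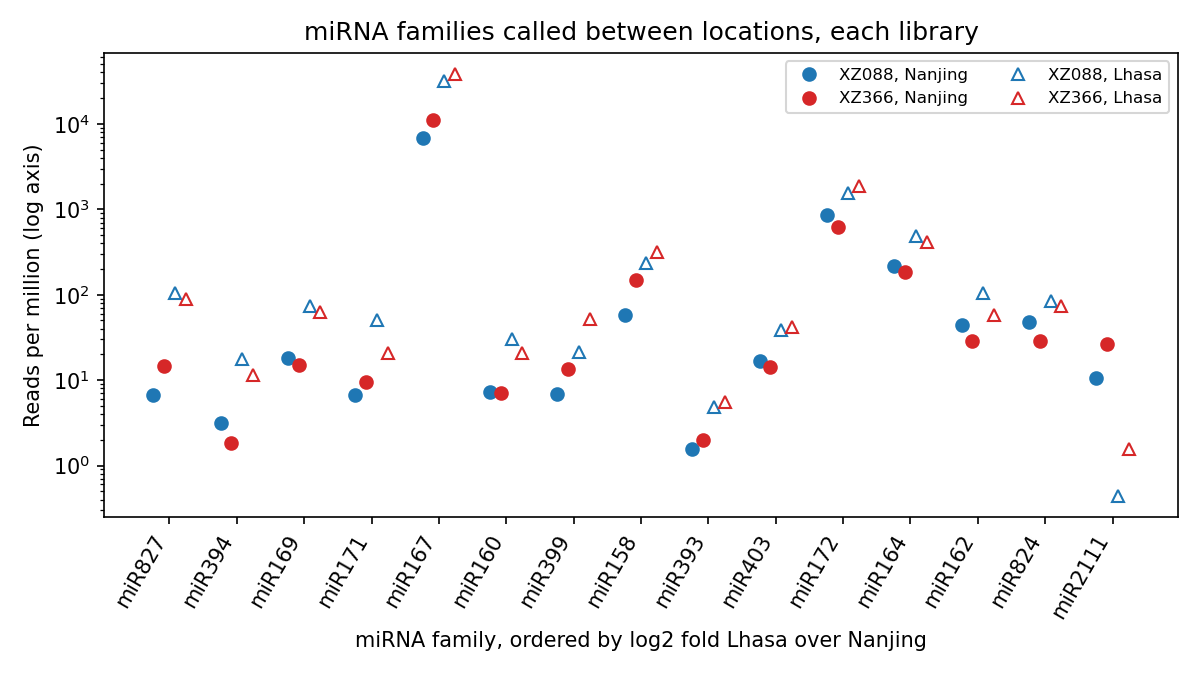
RPM (log axis) of the 15 families that passed between locations, in each library, ordered by fitted log2 fold. Both Lhasa libraries (open triangles) lie above both Nanjing libraries (filled circles) in 14 families and below them in miR2111.

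Outside the list, 13059 of 63595 tags differed between locations, 6773 higher and 6286 lower at Lhasa. Scaled by total reads, 13039 passed, of which 27.6% were higher at Lhasa, against 51.9% under TMM. With DESeq2 1947 tags passed, and 5643 after thinning to equal depth. Of the 3 tags with the smallest p among those higher at Lhasa, 2 were close to an adapter. TTCAGAGTTCTACAGTCCGGACGATC, with 587 and 1485 reads in XZ088 and XZ366 at Lhasa and 0 at Nanjing, lies 2 edits from the end of the Illumina 5-prime adapter. TTCAGAGTTCTACAGGTCCGACGATC, with 300 and 754 reads at Lhasa, lies equally close. The 15-nt tag GGGGGGACGACGATT went from 11 and 21 reads to 804 and 1904. Against a floor of 3 reads over both Nanjing libraries, the adapter tags were at least 1456-fold and at least 740-fold higher. Reads like the adapter numbered 18 and 21 at Nanjing and 5304 and 5141 at Lhasa, and reads shorter than 18 nt took 0.312% and 0.497% against 1.94% and 1.51%. The 3 leading tags in the other direction had 0 reads at Lhasa. TATGATAGTAGAAAACGAAC counted 403 reads in XZ088 and 351 in XZ366 at Nanjing, TGGACTCGAGGGCATCATCGC 433 and 270, and GACTGTTAGGCTGTAAAGCGG 477 and 205. They were at least 119-fold, 111-fold and 108-fold lower at Lhasa. The first of these 3 is an abundant 21-nt tag without its first base. That longer tag counted 1251 and 1127 RPM in XZ088 and XZ366 at Nanjing and still 304 and 522 at Lhasa. The 119-fold bound therefore holds for the shorter form only. Location calls carry 2 limits. Without cultivar as a block no family and no tag passed over all features, although 15 families and 17366 tags had an unadjusted p under 0.05 in edgeR, and 15 families passed over the list alone. Both Lhasa libraries also shared the adapter reads above, so library preparation and location cannot be told apart.

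Cultivar was compared as XZ366, the high-oil cultivar, over XZ088 with location as a block. None of 28 families passed over all features or over the list alone in edgeR, with 6 at an unadjusted p under 0.05, and DESeq2 called 1, miR157. This family, which targets SPL transcription factors, had the smallest p, with a log2 fold of 1.14 (SE 0.34, adjusted p = 0.0639 over all features and 0.112 over the list). XZ366 had 2.33 times the miR157 reads of XZ088 at Nanjing (counting interval 2.21 to 2.46) and 2.06 times at Lhasa (1.81 to 2.34). With 1 mismatch allowed the miR157 fold was only 0.17, as the more abundant tag TTGACAGAAGAAAGAGAGCAC then joins the family, and this tag had a cultivar log2 fold of 0.078. The related miR156 had 3.03 times (2.87 to 3.19) at Nanjing but 0.911 times (0.856 to 0.969) at Lhasa. The 5 tested nutrient families had positive fitted folds, none called, but miR827 was 2.14 times as high in XZ366 at Nanjing and 0.854 times (0.722 to 1.01) at Lhasa. The fitted log2 folds were miR2111 at 1.41, miR408 at 1.20 (0.67 to 1.65 with each library left out), miR399 at 1.14, miR397 at 0.66 (0.19 to 1.19) and miR827 at 0.39. Their median of 1.14 lay at the 99.9th percentile of random tag lists, as a description of these libraries.

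Lower values in XZ366, also not called, were those of miR390 at -0.99 (SE 0.35, adjusted p = 0.142), miR162 at -0.74, miR394 at -0.68 and miR824 at -0.47. miR158 had 0.91 (0.44 to 1.42 with each library left out) and miR391 0.52. The young Brassicaceae list had a median of 0.52, at the 99.2nd percentile. Of its 5 tested members the highest fold, 1.14, was that of miR157, which is near-identical to miR156. Of the 14 development families tested, 4 had a positive fold and the median was -0.24, at percentile 7.60. Within it miR159 had -0.31, miR160 -0.28, miR166 -0.26, miR169 -0.24 and miR164 -0.23. Of these, miR169 turned to 0.71 for exact listed sequences and miR160 to 0.027 without either Lhasa library. Auxin families had a median of 0.014 with a mean of -0.049, and silencing families a median of -0.065, near the middle of random lists. The abundant miR167 had 0.49 (adjusted p = 0.702), miR168 -0.065, miR172 -0.10 and miR156 0.74, the last 3 of which changed sign when a library was left out, and miR1885 had 0.092. The lone tested trigger and resistance families were miR390 and miR1885.

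Single tags outside the list did separate the cultivars. Of 63595 tags, 3639 passed, 2365 higher and 1274 lower in XZ366 (edgeR, adjusted p under 0.05). Scaled by total reads 2416 passed, and with DESeq2 602. The 3 with the smallest p were 24-nt tags with 0 reads in both XZ088 libraries. GGGAATGGAGTCCGAGCAGAACGT had 1251 reads in XZ366 at Nanjing and 196 at Lhasa, ATCGGGACATTAGCAGCAGTGGAG had 906 and 220, and TGTAGCTGAACGGCAACCTCGAAC had 851 and 218. Against a floor of 3 reads over both XZ088 libraries they were at least 403-fold, 313-fold and 297-fold higher in XZ366 (adjusted p = 1.04e-05 for each). In the other direction, AAGAGACAATACAGCACCTGCTAC had 379 and 47 reads in XZ088 and 0 and 1 in XZ366, a ratio of 510 (counting interval 91.1 to 20201). ATGAAGGACCAAAAAGCACGCGCA had 262 and 31 reads against 0 and was at least 117-fold lower in XZ366. AGAAGGTTTCATGCAGACTGCACA had 227 and 12 reads against 1 and 0, a ratio of 286 (50.9 to 11354). Without location as a block no tag passed, with 3390 at an unadjusted p under 0.05. Thinned to equal depth, 1112 tags passed, and 5876 without the count filter.

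A count of tags present in a pair of libraries and absent from the other pair, made after the values were seen, was also uneven. It uses the same libraries as the fits and is no separate evidence. With at least 10 reads in both XZ366 libraries and 0 in both XZ088 libraries there were 1312 tags, against 18 with the cultivars exchanged. The XZ366 set held 1.06% of that cultivar's reads at Nanjing and 0.813% at Lhasa, and 24-nt tags held 80.9% of its reads. Between locations, 1513 tags were in both Nanjing libraries alone and 186 in both Lhasa libraries alone, of which 77 were adapter-like or 1 mismatch from a far more abundant tag, against 10 of the Nanjing set. In the Nanjing set 21-nt tags held 55.2% of the reads and 24-nt tags 14.1%. The diagonal pairings, which follow neither factor, gave 1 and 0. With all libraries thinned to 2252748 reads the counts were 505 for XZ366, 17 for XZ088, 291 for Nanjing and 185 for Lhasa.

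**Figure D3:**
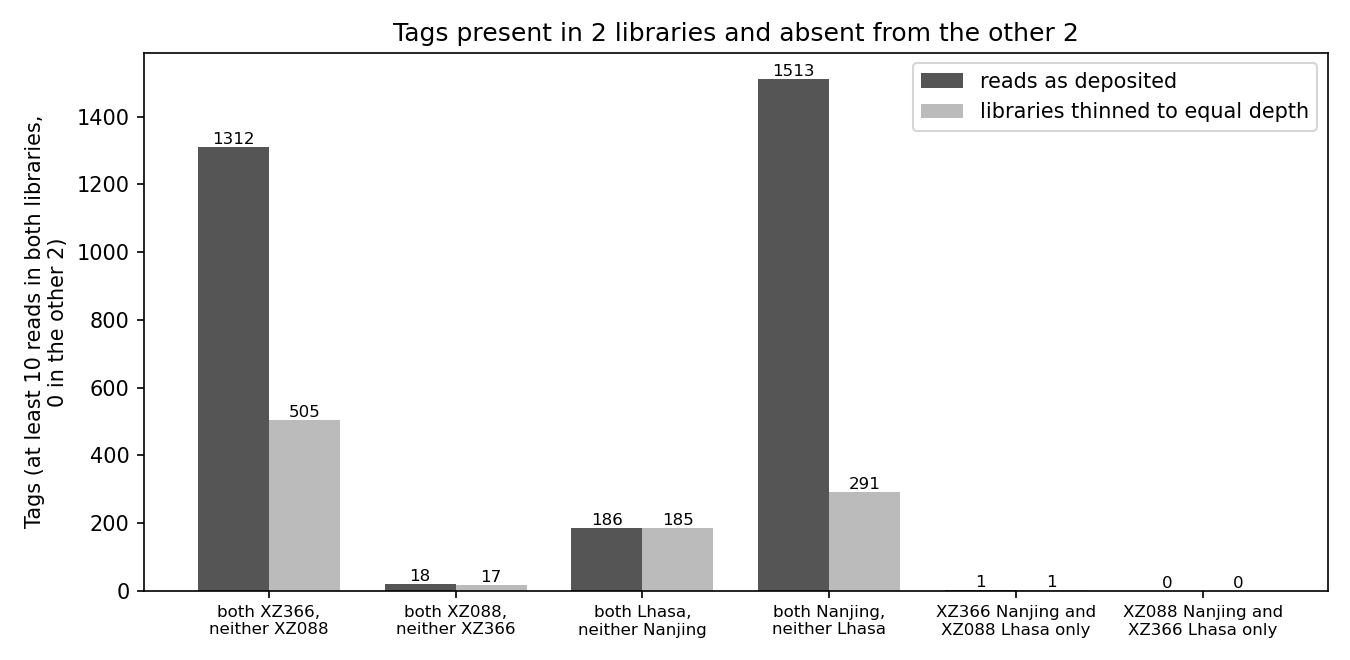
Number of tags (y axis) with at least 10 reads in both libraries of a pair and 0 in the other 2, for each pairing of the 4 libraries, as deposited (dark bars) and thinned to equal depth (light bars). XZ366 has 1312 such tags against 18 for XZ088, and 505 against 17 at equal depth.

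**Figure D4:**
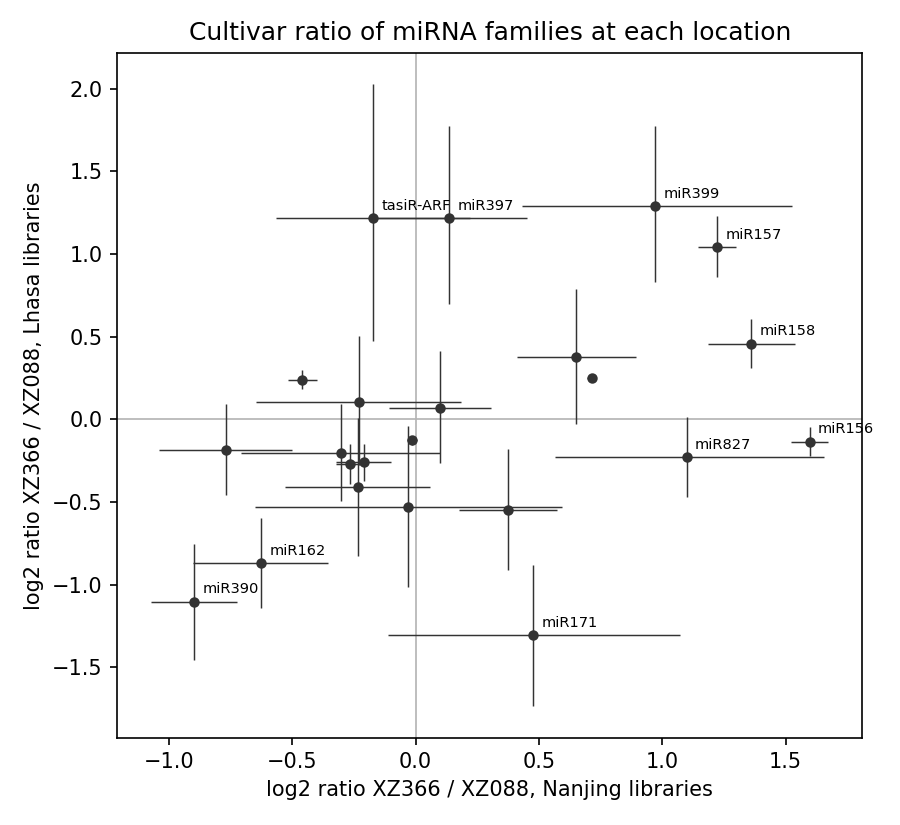
log2 ratio of RPM, XZ366 over XZ088, of the 23 families with a mean of at least 10 RPM, in the Nanjing libraries (x axis) and the Lhasa libraries (y axis), with 95% counting intervals. Most families lie in the quadrants of equal sign, and miR156 is at 1.60 and -0.13.

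The effect of each factor was then compared between the levels of the other, across families, which are not independent replicates. Cultivar ratios at the 2 locations correlated with r = 0.39 (p = 0.0700, permutation test, 23 families; rho = 0.44, p = 0.0387), and 69.6% of families had the same sign. Adjusted over the 4 coefficients computed, these p-values were 0.0700 and 0.0517. Without the 2 families farthest from the median on the x axis r was 0.44. Location ratios in the 2 cultivars correlated with r = 0.82 (p = 2.00e-05, permutation test; rho = 0.77, p = 5.00e-05), with adjusted values of 8.00e-05 and 1.00e-04. There 87.0% of families had the same sign, and r was 0.76 without the 2 farthest. The 2 ratios of a pair share no library. Both location ratios do set a Lhasa library with many adapter reads over a Nanjing library with few. A preparation or run shared by the Lhasa libraries could thus also give this agreement. The difference of the 2 log2 ratios, which has no test in this design, was largest for miR171, at -1.78 for Lhasa minus Nanjing. Its cultivar ratio was 1.39 at Nanjing (0.926 to 2.10) and 0.405 at Lhasa (0.300 to 0.544). miR156 followed with -1.73, miR396 with 1.45, the auxin-directed siRNA with 1.39 and miR827 with -1.33. The same 5 differences hold for location between the cultivars, since both are the same contrast of 4 libraries. The Lhasa over Nanjing ratio of miR171 was 7.53 in XZ088 and 2.19 in XZ366, and that of miR827 was 15.6 and 6.21.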

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

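Of the tests given here, that of a sequencing run shared by the Lhasa libraries was chosen after the result was seen. The equal-depth setting and the removal of adapter-like, short and mismatched tags, first outside and then also within families, were also added after seeing the data.

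In ratios of RPM, which are scaled by total reads, 4 families had opposite signs of a factor's effect in the 2 pairs of libraries, each beyond its counting interval. For cultivar, the Lhasa minus Nanjing difference of log2 ratios was -1.73 in miR156, -0.92 in miR165 and 0.70 in miR172. For location, the XZ366 minus XZ088 difference was -1.73 in miR156, which is the same contrast, and 1.08 in miR397. The location signs of miR156 depend on the scaling, as TMM raises every location fold by about 0.43 and miR156 is then 0.035 or higher with each library left out. For miR397 the XZ088 log2 ratio was -0.56 (counting interval -1.11 to -0.045). Its sign would stay negative after that shift, but with an interval that includes 0. With 1 library on each side these differences were not tested.

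The location calls stood beside signs of a technical difference between the libraries. Reads like the 5-prime adapter numbered 5304 in XZ088 and 5141 in XZ366 at Lhasa, against 18 and 21 at Nanjing. Thinning to equal depth left 93.3% of the 15 called families, which argues against depth for the families. Of all 13074 called features, 7494 were still tested there, and 70.1% of these stayed called. Thinning itself removes reads, so depth stays open for the single tags. Removing adapter-like, short and mismatched tags, members of families included, took 13161 of 516137 family reads in 23 families. This removal left 100% of the family calls and 90.6% of the called features outside such tags, which argues against these tags. Pooled over sites, the abundant tags other than miR167 carried A-to-C mismatches at 0.0356% and 0.0308% at Nanjing and 0.649% and 0.541% at Lhasa, at least 17.5 times as often in either cultivar. Over all 30 abundant tags the median site went from 0.0141% and 0.0105% at Nanjing to 0.0592% and 0.101% at Lhasa, a smaller rise. A preparation or sequencing run shared by both Lhasa libraries therefore may account for some of the calls, and it cannot be told apart from the field location, whose effect stays open and untested.

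With the block kept, 4 libraries allow 2 splits, too few for a share under 0.05. For location, 1 of the 2 splits, the real one, called 13059 tags, and the other split called 0. For cultivar the real split called 3639 tags and the other 0, so again 1 of 2. In each other split the real factor becomes the error term. Its effect then widens the spread and can bring the count to 0, so neither 0 is a control.

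Reads that start with a listed animal or monocot miRNA numbered 16 in XZ088 and 57 in XZ366 at Nanjing, and 30 and 55 at Lhasa, all above the 3 reads that a count of 0 allows. Passenger strands, which the comparisons did not use, outnumbered the listed mature strand in all 4 libraries in 3 families. Their totals were 10049 reads for miR408, 1511 for miR160 and 834 for miR396, against 131, 240 and 150 mature reads.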

How the results depend on the processing

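No paired analysis was possible because the groups, of 1 library each, share only the replicate number 1. The block in the fits is the other factor, not a replicate. Fits without a library leave no residual degree of freedom and gave folds with no call. Each such fold is set by the pair of libraries that stays whole. Apart from scaling it restates the ratio within that pair, so it is no separate check of robustness. The share of reads matching a genome was planned and not run, as no genome was used. Equal depth and removal of adapter-like, short and mismatched tags, with or without those in families, were chosen after seeing the data. The cause of each shift was not tested unless given.

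The location count of 15 families was between 11 and 17 under total reads, DESeq2 size factors, DESeq2, exact sequences, 1 mismatch, families alone, equal depth and tag removal. The members also changed. With 1 mismatch miR169 lost its call, its fold going from 2.48 to 0.61. With exact sequences miR827 was not tested. Families alone gave 11, of which 7 were higher and 4 lower, with TMM computed from the families. There 7 of the 15 lost their call (miR158, miR162, miR171, miR172, miR393, miR403 and miR824) and miR157, miR166 and miR390 (-1.35) were called as lower. The count was 6 without the count filter, which tests 532284 features and ends 9 of the calls, and 0 without the block, where the cultivar effect enters the error. The cultivar count of 0 families became 1, miR157, with DESeq2 and was 0 elsewhere. The miR157 cultivar fold of 1.14 was 0.17 with 1 mismatch. Cultivar tags numbered 3639, but 2416 under total reads, 5876 without the filter, 0 without the block, 1112 at equal depth, where 27381 tags were tested, and 602 with DESeq2, which gave no adjusted p for 29604 features. Location tags numbered 13059, but 0 without the block, 5643 at equal depth and 1947 with DESeq2. Of the 15 location families, 13 were kept under total reads and 14 at equal depth, where miR393 lost its call. With DESeq2 miR393 also lost its call, and 3 named families gained one, miR157 and miR166 among them. The cultivar agreement by Pearson's r, 0.39, passed the threshold at a minimum of 1 RPM (0.43) and with a pseudocount of 10 (0.44). It did not at a minimum of 100 or a pseudocount of 0.1. For location r was 0.82 to 0.84 and passed in each, while rho did not at a minimum of 100 (p = 0.0578).

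Values for libraries follow in the order XZ088 Nanjing, XZ366 Nanjing, XZ088 Lhasa, XZ366 Lhasa. The 24-nt share was 42.8, 42.8, 38.4 and 40.8% of distinct sequences, 53.2, 51.3, 43.8 and 45.1% of 18 to 28 nt reads, 56.3, 53.8, 47.5 and 47.0% without tags seen once, and 53.1, 51.2, 42.9 and 44.5% without transfer and ribosomal RNA. The 21-nt share was 12.3, 11.3, 13.5 and 12.7% of distinct sequences, 13.3, 13.0, 18.3 and 17.6% of 18 to 28 nt reads and 13.6, 13.4, 21.3 and 20.1% without tags seen once. Their ratio was 3.48, 3.77, 2.84 and 3.21 for distinct sequences, 4.13, 4.01, 2.23 and 2.33 without tags seen once, and 4.01, 3.98, 2.41 and 2.57 without transfer and ribosomal RNA. Both Lhasa libraries had the lower 24-nt share and ratio and the higher 21-nt share in each setting. The cultivar difference of the 24-nt share at Lhasa changed sign without tags seen once. Family RPM were 15972, 21200, 46656 and 51951 over 20 to 25 nt reads, and 10505, 15377, 35051 and 41615 for exact sequences.

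Of 21 families named for cultivar and 25 for location, 6 and 5 changed sign somewhere, none of them called in that comparison. Cultivar folds reversed for miR1885 (-0.027 with 1 mismatch), miR169 (0.71 for exact sequences), miR168 (0.11 without the filter) and miR172 (0.068 without the filter, 0.063 without the block). Ranges with a library left out restate the folds within the whole pairs, as given above. With each library left out in turn, the fold ran from -0.15 to 0.042 for miR168 and from -0.55 to 0.027 for miR160, reversed without either Lhasa library. It ran from -0.40 to 0.22 for miR172 and from -0.16 to 1.65 for miR156, reversed without either Nanjing library. Location folds reversed for miR165 (0.058 with 1 mismatch, 0.15 at equal depth) and miR391 (-0.29 under total reads, -0.57 without the filter, -0.73 for families alone). They also reversed for miR1885 (-0.20, -0.49 and -0.64 in the same settings), miR159 (-0.16 without the filter, -0.32 for families alone, -0.17 for exact sequences) and miR168 (-0.030 without the filter, -0.19 for families alone). With libraries left out miR165 ran from -0.68 to 0.31, reversed without either XZ366 library (0.28 without XZ366 Lhasa), and miR391 from -0.018 to 0.32, reversed without either XZ088 library. Other folds moved without a change of sign. For cultivar these were miR158 (0.44 to 1.42), miR397 (0.19 to 1.19) and miR408 (0.67 to 1.65). For location they were miR156 (0.035 to 1.83), miR158 (1.52 to 2.48), miR171 (1.54 to 3.37), miR396 (0.47 to 1.88) and miR827 (3.04 to 4.42). The shallowest library limits what can be seen: 3 reads there are 1.33 RPM, and 11 listed families were too rare to test.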

Other observations

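Of the tests given here, those of a virus origin and of sequencing error were chosen after the result was seen. The patterns themselves were noticed in these data, so each reading of them is a hypothesis.

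Passenger strands showed their own levels. The strand opposite miR408, a copper-linked family, counted 466 and 731 RPM in XZ088 and XZ366 at Nanjing and 271 and 460 at Lhasa, higher in XZ366 at both. Its mature strand stayed between 3.31 and 10.1. The opposite strand of miR396 counted 22.4 and 25.1 at Nanjing and 109 and 74.5 at Lhasa, and that of miR168 4.58 and 12.7 against 44.4 and 62.2. Single-base variants of families also differed between libraries. The tag TTGACAGAAGATAGAGAGCAC, the listed miR157, differs from the more abundant TTGACAGAAGAAAGAGAGCAC by A12T, counted from the 5-prime end. It took 5.68% of both at Nanjing and 6.20% at Lhasa in XZ088, against 12.4% and 11.2% in XZ366. The upper ends of its XZ088 intervals, 5.93% and 6.93%, lay below the XZ366 interval at Lhasa of 10.5 to 11.8%.

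By mean RPM over the 4 libraries, the most abundant tag outside every list was CTTTGTCTATCGTTTGGAAAAG, of 22 nt, at 6792 and 7906 RPM at Nanjing and 1290 and 3528 at Lhasa. It fell at Lhasa by 1.34 on the log2 scale (SE 0.39, adjusted p = 0.0257 in edgeR), in both cultivars. ATATGATAGTAGAAAACGAAC, of 21 nt, counted 1251 and 1127 at Nanjing and 304 and 522 at Lhasa, and fell by 1.14 (SE 0.36, adjusted p = 0.0363). Neither is within 5 edits of a listed sequence. The nearest to the 22-nt tag, at 6 edits, was the passenger strand of miR158, a family that itself rose by 2.00 at Lhasa. Whether the 22-nt tag comes from a miR158 locus was not tested. The 21-nt tag, without its first base, is the 20-nt tag with 0 reads at Lhasa given above.

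The 1312 tags seen only in XZ366 (at least 10 reads in both) were weighed. At equal depth they outnumbered those seen only in XZ088 by 29.7 times, which argues against depth. Tags of 24 nt held 80.9% of their reads, and tags of 21 and 22 nt 1.21% and 5.72%. Most of these reads are thus not virus-derived small RNAs of 21 and 22 nt. The share was known when the virus test was chosen, and length alone does not decide the origin of these 1312 tags. A partner of 1 mismatch in both XZ088 libraries existed for 13.2% of them (173 tags) and for 157 of 1312 tags found in all 4 libraries. Of the 1513 tags seen only at Nanjing, 71 had such a partner at Lhasa. The 13.2% lies between the bounds of 10% and 50% set beforehand, so the test did not decide. Single-base variants stay open for at most those 173 tags, as the rest had no such partner. Overlaps of 16 nt joined 82.6% of the XZ366 tags into shared stretches, against 63.3% of the tags seen only at Nanjing. However, 993 of the 1312 XZ366 tags but 313 of the 1513 Nanjing tags were 24 nt long. Longer tags leave more room for such an overlap, and length was not matched, so nothing is concluded from this gap. The joined share was 40.9% for the 1312 tags found in all 4 libraries, but these are a part of 182489 such tags. Neighbours left out of a part cannot be joined, so that share cannot be set against the others. A candidate explanation is a set of siRNA-producing loci that XZ088 lacks or does not express, which is a cultivar difference that was not tested here.

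The miR172 family shifted between its 3-prime ends. AGAATCTTGATGATGCTGCAG, which differs from AGAATCTTGATGATGCTGCAT by T21G counted from the 5-prime end, took 17.6% and 18.8% of both tags at Nanjing and 41.3% and 41.0% at Lhasa in XZ088 and XZ366. Inner T-to-G mismatches of abundant tags reached at most 0.0250% at Lhasa, which argues against sequencing error. In 6 other pairs of tags that end in G or T the median log2 shift toward G was -0.24 (bootstrap interval -0.59 to 0.024) against 1.65 for miR172, which argues against a general end preference. Unequal expression of miR172 loci at the locations may remain as an explanation, beside any other difference of the Lhasa preparation, and neither was tested.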
